A study of Homo sapiens with 6 samples.

How the data were processed

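RNA was measured by strand-specific sequencing of polyA-selected libraries from C4-2B cells, a human prostate cancer line derived from LNCaP. Stable sublines carried either the empty pcDNA 3.1 vector (3 libraries) or the same vector with LINC00888 (3 libraries). Paired ends were read for 150 cycles. The submitters' processing notes name FastQC, cutadapt, HISAT2 and StringTie, without versions, and GRCm38, a mouse build, as the only genome build. The deposited files do not carry mouse features: their 11844 genes and 29964 transcripts have human Ensembl identifiers, all annotated as protein coding. Of the gene identifiers, 11717 carry the suffix that GENCODE gives to its annotation mapped to GRCh37. For 11765 genes the identifier was found in a GRCh38 annotation, and the start and end were equal in 86 of them. The positions printed here are those of the deposited tables, whose build is not stated.

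Values are FPKM per the file headers, that is fragments normalised to model length and to mapped fragments, computed by the authors for each library on its own, with no further scaling recorded. A test on the values showed that each listed feature had a mean FPKM of at least 0.5 in at least 1 of the 2 groups. The smallest such mean was 0.500091 for genes and 0.500076 for transcripts. A transcript line of the deposited table was emptied for this work and was not used. The tables hold no counts, so the depth of the libraries is unknown and no counting intervals were computed.

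Features with an FPKM of at least 0.5 in at least 3 of the 6 libraries were kept, which left 11726 genes and 26941 transcripts. Values were taken as log2(FPKM + 0.5), without rescaling between libraries, and the groups were compared with limma (lmFit, then eBayes with trend and robust), two-sided, with Benjamini-Hochberg adjustment and a threshold of an adjusted p under 0.05. The pseudocount makes the log2 fold changes of genes with low FPKM smaller than the ratio of their means. Folds of single genes in the text are ratios of mean FPKM. Log2 fold changes, and counts of features with at least a 2-fold change unless the ratio is named, are those of the fit. Gene lists were tested with limma's camera at a preset correlation of 0.01, over lists with at least 5 kept members. Alternatives were camera with the correlation estimated from the data, and fry. Genes within 1 Mb of LINC00888 were taken by identifier from the GRCh38 annotation.

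The gene lists, 42 in all, the tests and most alternatives were fixed before the data were examined. The lists covered androgen response, luminal, basal, neuroendocrine, fibroblast, leukocyte and endothelial markers, mesenchymal (EMT) genes, G1/S, G2/M, MYC targets and nucleolus, ribosomal proteins, mitochondrially encoded genes, nuclear oxidative phosphorylation and histones. They also covered interferon, MHC class I, TNF and NF-kB, immediate early, MAPK, p53, apoptosis, unfolded protein, integrated stress, heat shock, hypoxia, glycolysis, cholesterol, fatty acid synthesis, fatty acid oxidation, NRF2 and steroid metabolism genes. The rest were WNT, NOTCH, TGF-beta, YAP, PRC2, splicing, autophagy, proteasome, cadherin, and integrin and matrix lists. The genes named in the text followed a rule. It took the 12 largest rises and 12 largest falls, ranked by the log2 fold change of the fit, among genes past the threshold with an FPKM of at least 1 in all 3 libraries of the higher group and no overlap between the groups. From each list past the threshold it took up to 4 members with the smallest p, and from other lists up to 2 where at least 1 passed. For transcripts it took the 5 largest rises and 5 largest falls by the fit. Some genes that the rule took are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

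The procedure was tested on simulated data made from the spread of these libraries, with 50 changed features at each fold. Among genes it recovered 30% of 1.25-fold, 66% of 1.5-fold, 80% of 2-fold and 96% of 3-fold changes, with 7 false calls. Among transcripts it recovered 0%, 2%, 8% and 22%, with 2 false calls. The simulated noise was normal and drawn for each feature and library on its own, without jumps of features between levels. False calls in the real data may thus be more frequent: splits of the real libraries that mix the groups called between 19 and 53 transcripts. A shifted list was called among genes (adjusted p = 1.36e-11) and missed among transcripts (adjusted p = 0.065), and 0 of 40 unshifted lists were called. Because features were simulated independently, this cannot show how often lists whose members move together are called falsely. In the real lists that passed camera, the estimated correlation ran from -0.0253 (glycolysis) to 0.211 (proteasome).

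The alternatives tried were pseudocounts of 0.1 and 1, no filter, a stricter filter at an FPKM of 1, median ratio scaling, quantile normalization, eBayes without trend and robust, the replicate number as a block, a 2-fold minimum and leaving out each library in turn. Cyclic loess normalization, leaving out genes that span 2-fold within a group and leaving out part of chromosome 16 were added after seeing the data. Tools were R 4.3.3, limma 3.58.1 and GenomicRanges 1.54.1, with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 for the figures. The GRCh38 annotation also gave overlaps between genes, transcript lengths and GC content, joined by identifier. The level of LINC00888 was not analysed here, because the tables list protein-coding features.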

Results

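Gene expression was measured in C4-2B prostate cancer cells that stably carried LINC00888, a long noncoding RNA, or the empty vector, with 3 libraries in each group. C4-2B is a line derived from LNCaP that grows without added androgen. The comparison asks which transcripts differ when LINC00888 is expressed from a vector. By the labels, quantitative PCR on the same RNA gave a LINC00888 level 15.27 ± 2.4 times that of the control (SD, number of measurements not stated). Its level in the sequencing data was not analysed here. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries. Nor do they tell sublines within a group apart, so any other difference between the sublines coincides with the groups. The FPKM of the listed genes summed to between 211148 and 217637 per library, the median gene had an FPKM between 5.83 and 6.15, and 10671 to 10869 genes reached an FPKM of 1. Sequencing depth is unknown. Correlation of log2 values across genes was 0.985 for each pair of libraries within a group and 0.977 to 0.98 between groups, and the first principal component, with 36.7% of the variance, separated the groups. Mitochondrially encoded transcripts made up 17.6%, 17.7% and 18.4% of the FPKM sum in the empty vector libraries and 18.4%, 18.9% and 19.7% in the LINC00888 libraries. These shares did not overlap between groups (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 allows).

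With LINC00888, NIPSNAP1, a mitochondrial protein that takes part in mitophagy, rose 3.32-fold, from 23.7 ± 0.26 to 78.5 ± 1.05 FPKM (SD, n = 3; adjusted p = 1.11e-05). ADNP, a homeobox protein of chromatin, rose 3.37-fold, from 5.76 ± 0.74 to 19.4 ± 1.08 FPKM (adjusted p = 0.000872). SESN3, a stress-responsive regulator of mTORC1, rose 3.04-fold, from 9.32 ± 1.01 to 28.3 ± 1.98 FPKM (adjusted p = 0.0011). TMEFF2, a membrane protein with follistatin-like domains that is expressed in prostate and brain, fell 66.3-fold, from 3.02 ± 0.16 to 0.0455 ± 0.018 FPKM (adjusted p = 6.61e-05). The cancer-testis antigen CTAG2 fell 12.9-fold, from 3.91 ± 0.64 to 0.303 ± 0.035 FPKM (adjusted p = 0.000448). The alpha-2A adrenergic receptor ADRA2A fell 4.78-fold, from 8.55 ± 0.44 to 1.79 ± 0.14 FPKM (adjusted p = 0.00016).

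Among the other largest rises by the fitted log2 fold change, lipoprotein lipase (LPL) went from 13.2 to 28.7 FPKM, CRISP3, a secreted protein of the male reproductive tract, from 8.77 to 19.0, the cytochrome P450 CYP4F8 from 3.06 to 9.78 and the vesicle protein SYT4 from 2.28 to 6.56. PEBP4 (2.51 to 5.85), the sulfotransferase CHST15 (0.658 to 1.90), the germ cell protein NANOS3 (0.54 to 1.84), sulfite oxidase SUOX (2.44 to 7.27) and ATRIP, the partner of the kinase ATR (0.424 to 1.57), completed the 12 largest. The largest falls by the same measure took in 2 genes of the cytoskeleton and its motors, ARPC5 of the Arp2/3 complex (18.6 to 7.19) and DCTN4 of dynactin (19.6 to 6.22), and the matrix protein fibronectin, FN1 (28.6 to 12.02). The organic cation transporter SLC22A3 (16.4 to 6.67), R3HDM4 (16.2 to 6.64), the glucagon gene GCG (3.54 to 0.837), the ribosomal oxygenase RIOX1 (1.47 to 0.241), TMEM79 (5.96 to 1.84) and CHMP4A of the ESCRT machinery (1.53 to 0.35) were the others. Adjusted p-values of these genes lay between 0.000134 (SLC22A3) and 0.0289 (ATRIP). Leaving out 1 library ended the call of SUOX (without empty vector library 2 or any of the LINC00888 libraries, adjusted p up to 0.0681). It also ended those of ATRIP and TMEM79 (each without empty vector library 2 or 3 or LINC00888 library 1 or 2, up to 0.0941 and 0.0737) and CHMP4A (without empty vector library 1 or 3 or LINC00888 library 2, up to 0.0574). TMEFF2, CTAG2 and RIOX1 fell below the filter, and were not tested, without any of the empty vector libraries. NIPSNAP1, NANOS3, ATRIP, PEBP4 and CHMP4A overlap another annotated gene on the same strand, and CTAG2 has near-identical relatives whose reads it can share.

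**Figure D1:**
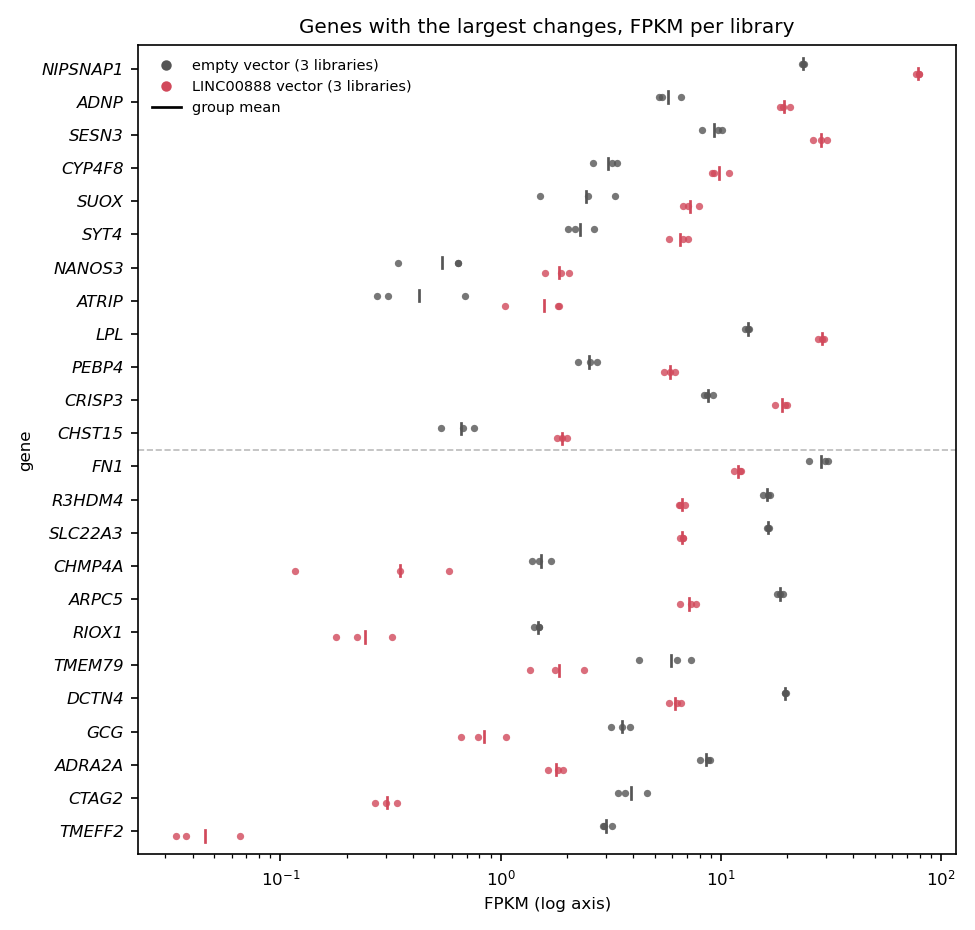
FPKM per library (log axis) of the 12 genes with the largest rise and the 12 with the largest fall in the fit; points are libraries, 3 per group, and vertical ticks are group means. The groups do not overlap for any of these genes, and TMEFF2 reaches the lowest level, a mean of 0.0455 FPKM with LINC00888.

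NIPSNAP1 (ENSG00000184117.11_3) lies on chromosome 22 at 29950797 to 29977326, ADNP (ENSG00000101126.15_3) on chromosome 20 at 49505456 to 49547777 and SESN3 (ENSG00000149212.11_3) on chromosome 11 at 94898677 to 94965705, in the positions of the deposited tables. TMEFF2 (ENSG00000144339.11_2) lies on chromosome 2 at 192813769 to 193060435, CTAG2 (ENSG00000126890.13_2) on chromosome X at 153880246 to 153881853 and ADRA2A (ENSG00000150594.6_3) on chromosome 10 at 112836921 to 112840665. Among 11726 genes tested with limma, 1581 (13.5%) passed the threshold, 941 higher and 640 lower with LINC00888. Most of these changes were small: their median absolute log2 fold change was 0.33, and 42 genes changed at least 2-fold in the fit, 19 higher and 23 lower. By the ratio of mean FPKM, without the pseudocount, 119 of the 1581 did, 78 higher and 41 lower. In 38.3% of tested genes the groups did not overlap, where chance gives 10%. The balance of directions depended on the scaling between libraries, with 760 genes higher and 814 lower after median ratio scaling, 688 and 648 after quantile normalization, and 686 and 669 after cyclic loess. Leaving out 1 library left between 536 genes (without LINC00888 library 1) and 815 (without empty vector library 1), and each of the 6 moved the count by over 1.5 times. It was 811 and 612 without empty vector library 2 or 3, and 614 and 697 without LINC00888 library 2 or 3. With the replicate number as a block 429 genes passed.

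Heat shock proteins and chaperones were lower on balance. The cytosolic chaperone HSP90AB1 went from 775 ± 10.8 to 632 ± 8.6 FPKM (SD, n = 3; adjusted p = 0.0045). Its cochaperone STIP1 went from 68.4 ± 1.17 to 55.6 ± 0.86, HSPH1 from 40.4 ± 0.72 to 32.9 ± 0.65 and the small heat shock protein HSPB1 from 503 ± 8.7 to 408 ± 17.1. Of 20 members, 12 fell, 0 rose and all 20 had a lower estimate (16 fell and 0 rose adjusted over the list alone), with a median log2 fold change of -0.18. The list passed camera (adjusted p = 3.86e-11) and not camera with an estimated correlation (adjusted p = 0.113). Quantile normalization ended the call of HSP90AB1 (log2 fold change -0.02, adjusted p = 0.59). The 7 lists past the threshold, all lower with LINC00888, had a median member FPKM between 20.1 and 60.2, and across all genes the fold change fell with expression level, from a median of 0.12 in the lowest decile to -0.05 in the highest.

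Proteasome subunits, which degrade ubiquitin-tagged proteins, were lower by small amounts: 29 of 30 had a lower estimate, with a median log2 fold change of -0.13. Past the threshold were 3, the regulatory subunits PSMD3 (34.3 to 29.6 FPKM) and PSMC1 (28.2 to 23.8) and the core subunit PSMA7 (156 to 139). PSMC2, at 58.7 and 52.4 FPKM, did not pass (adjusted p = 0.0501). Adjusted over the list alone, 7 fell and 0 rose. The list passed camera (adjusted p = 7.42e-07) and not with an estimated correlation (adjusted p = 0.376). Each of the 6 left-out libraries ended the calls of PSMD3 and PSMA7 (adjusted p up to 0.0699 and 0.0948), and leaving out empty vector library 3 or any LINC00888 library ended that of PSMC1 (up to 0.0732). Quantile normalization and cyclic loess also ended the call of PSMA7.

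The MYC target and nucleolus list and the G2/M and mitosis list were lower on balance by camera with the preset correlation. Among MYC targets and nucleolar genes, the polyamine enzymes SRM (63.9 ± 1.22 to 50.9 ± 1.41 FPKM, SD, n = 3) and ODC1 (143 ± 4.2 to 115 ± 2.2) and the ribosome assembly factors RRS1 (44.4 to 35.1) and NOP56 (32.2 to 26.7) were lower. Of 38 members 12 fell and 0 rose (17 fell and 1 rose adjusted over the list alone), with a median log2 fold change of -0.16 (camera adjusted p = 4.89e-07; adjusted p = 0.0702 with an estimated correlation). MYC itself had FPKM values of 48.3, 3.05 and 3.64 in the empty vector libraries and 39.3, 3.76 and 3.95 in the LINC00888 libraries (adjusted p = 0.994; chosen after its values were seen). Among mitotic genes, the anaphase activator CDC20 went from 64.4 ± 0.87 to 47.2 ± 0.29 FPKM, the kinase CDK1 from 97.7 ± 3.1 to 73.3 ± 1.9, the kinesin CENPE from 9.93 to 7.15 and the kinase PLK1 from 15.2 to 10.3. Of 40 members of the G2/M and mitosis list 12 fell and 0 rose, with the same counts adjusted over the list alone (median log2 fold change -0.08; camera adjusted p = 7.42e-07; adjusted p = 0.0702 with an estimated correlation). Genes of G1/S and DNA replication did not pass as a list: 1 of 40 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.193). CDC6 (19.3 to 16.8) and CLSPN (8.63 to 7.01) fell. The call of CDC6 was lost without each library but LINC00888 library 3 (adjusted p up to 0.0803) and that of CLSPN without each of the 6 (up to 0.087).

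Androgen-responsive genes moved in both directions. The elongation factor ELL2 fell from 25.7 ± 0.78 to 12.5 ± 0.21 FPKM (SD, n = 3; adjusted p = 0.000211), and the kallikrein KLK15 from 7.68 ± 0.46 to 3.73 ± 0.41. The serine protease TMPRSS2 rose from 82.3 ± 1.57 to 111.9 ± 1.31. Chosen after their values were seen, KLK3, which encodes prostate-specific antigen, also rose (372 to 409 FPKM, adjusted p = 0.0383), and KLK2 (92.7 to 74.7) and SLC45A3 (82.9 to 67.5) fell. The call of KLK3 was lost without each of the 6 libraries (adjusted p up to 0.129) and after median ratio scaling (0.0853). Of 35 members 3 rose and 9 fell (3 and 11 adjusted over the list alone), with a median log2 fold change of -0.03. The list was called lower by camera (adjusted p = 0.0349; adjusted p = 0.309 with an estimated correlation). That call was lost with the stricter filter (adjusted p = 0.0503), quantile normalization (0.532), cyclic loess (0.481), and without empty vector library 1 (0.0542) or LINC00888 library 2 (0.0676).

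Luminal markers were also mixed. The luminal keratins KRT8 (30.3 ± 0.89 to 24.4 ± 0.64 FPKM, SD, n = 3) and KRT18 (56.4 ± 0.76 to 46.0 ± 2.5) fell. Of 20 luminal members 3 rose and 3 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.4). Of 6 basal markers listed, the integrin ITGB4 (1.13 to 1.78) and the cadherin CDH3 (1.5 to 2.0) rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.332). Leaving out 1 library ended the calls of KRT18 (without LINC00888 library 1, adjusted p = 0.0513), ITGB4 (without each library but LINC00888 library 3, up to 0.0719) and CDH3 (each of the 6, up to 0.094). Quantile normalization and cyclic loess ended that of CDH3. Markers of other cell types were few: 3 neuroendocrine genes (ENO2, ONECUT2 and DDC), 4 fibroblast genes (COL1A1, PDGFRB, S100A4 and FBLN1), the leukocyte gene CD68 and the endothelial gene VWF were listed, too few to test as lists. Of these 9 genes, PDGFRB rose, from 0.308 to 0.65 FPKM (adjusted p = 0.0372, lost without each empty vector library, up to 0.0944, not tested without any of the LINC00888 libraries, and lost after quantile normalization, 0.104, and after cyclic loess, 0.0793). CD68 and VWF lay at 0.783 and 0.54 FPKM in the empty vector group and 0.719 and 0.522 with LINC00888.

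**Figure D2:**
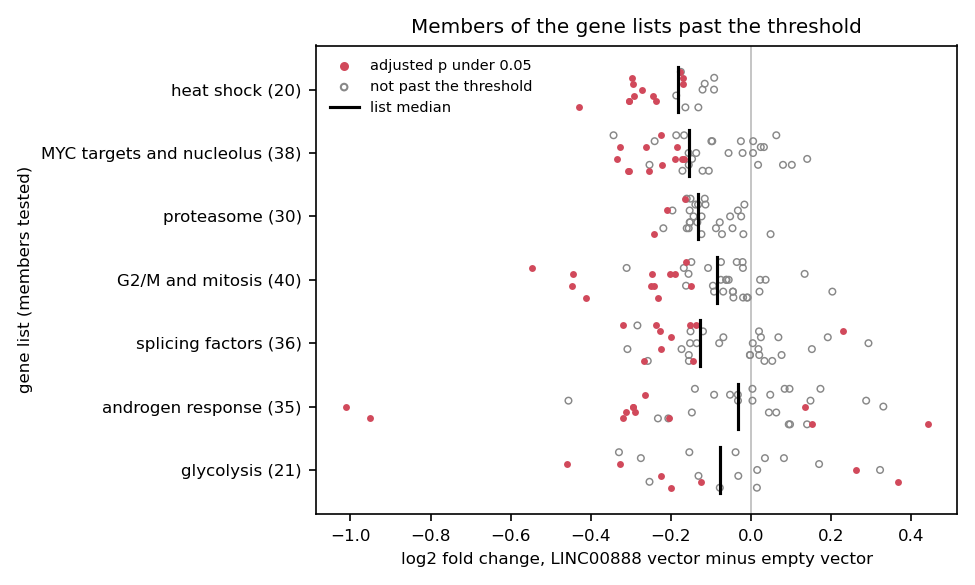
Log2 fold change (LINC00888 vector minus empty vector, 3 libraries each) of every tested member of the 7 gene lists past the threshold; filled points passed the test for single genes, open points did not, and black bars are list medians. Medians run from -0.18 (heat shock) to -0.03 (androgen response), and heat shock is the list in which all 20 members lie below 0.

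Splicing factors and glycolytic enzymes were lower on balance. Among splicing regulators, HNRNPK went from 130 ± 1.9 to 113 ± 0.87 FPKM (SD, n = 3), SRSF1 from 81.3 ± 1.6 to 69.5 ± 1.24, SRSF3 from 32.5 to 27.4 and HNRNPM from 54.8 to 43.8. Of 36 members 1 rose and 9 fell (2 and 13 adjusted over the list alone), with a median log2 fold change of -0.13 (camera adjusted p = 0.00199; adjusted p = 0.376 with an estimated correlation). In glycolysis, the lactate transporter SLC16A3 fell from 12.7 ± 0.25 to 9.12 ± 0.45 FPKM, GAPDH from 732 ± 18.5 to 584 ± 24.8 and PGAM1 from 199 ± 4.9 to 173 ± 2.8. The aldolase ALDOC rose from 28.2 ± 0.56 to 36.5 ± 2.04. Of 21 members 2 rose and 5 fell (3 and 8 adjusted over the list alone), with a median log2 fold change of -0.08 (camera adjusted p = 0.0431; adjusted p = 0.333 with an estimated correlation). Quantile normalization and cyclic loess ended the calls of the splicing list (adjusted p = 0.289 and 0.237) and of the glycolysis list (0.544 and 0.557). The glycolysis call was also lost with the stricter filter (0.0579), median ratio scaling (0.0537), the replicate block (0.0544) and without empty vector library 1 (0.0542), empty vector library 2 (0.0589) or LINC00888 library 1 (0.061). GAPDH lost its call under quantile normalization (log2 fold change -0.11, adjusted p = 0.122). SRSF3 lost it without empty vector library 3 or LINC00888 library 1 or 2 (up to 0.0529), HNRNPM without empty vector library 2 or 3 (up to 0.0546) and PGAM1 without empty vector library 3 or LINC00888 library 1 or 2 (up to 0.0635).

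In lipid metabolism, the fatty acid elongase ELOVL7 fell from 79.6 ± 0.85 to 59.6 ± 1.24 FPKM (SD, n = 3; adjusted p = 0.00203). The acyl-CoA synthetase ACSL3 fell from 96.8 ± 2.4 to 77.5 ± 2.0 and the acyl-CoA dehydrogenase ACADL from 13.6 ± 0.28 to 9.85 ± 0.48. The cholesterol carrier STARD4 fell from 8.30 to 6.72 and the peroxisomal enzyme EHHADH rose from 0.762 to 1.24. These calls were lost without empty vector library 3 or LINC00888 library 2 (STARD4, adjusted p up to 0.0574) and without LINC00888 library 1 or 2 (EHHADH, up to 0.0538). None of these lists passed. In cholesterol synthesis and uptake 1 of 24 rose and 4 fell (2 and 5 adjusted over the list alone; adjusted p = 0.171). In fatty acid synthesis 1 of 20 rose and 2 fell, the same adjusted over the list alone (0.193). In fatty acid oxidation and peroxisome 3 of 28 rose and 3 fell (4 and 3 adjusted over the list alone; 0.624). In the steroid and androgen metabolism list 1 of 11 fell, HSD17B10 (78.9 to 69.4), with the same count adjusted over the list alone (0.527), a call lost without each of the 6 libraries (up to 0.0933) and under quantile normalization and cyclic loess. The NRF2 antioxidant list had 1 rise and 1 fall among 18, the same adjusted over the list alone (0.375): ferritin light chain FTL rose from 209.9 to 244 and heme oxygenase HMOX1 fell from 17.3 to 14.5. Leaving out LINC00888 library 2 ended the call of FTL (adjusted p = 0.0526), and leaving out empty vector library 3 or LINC00888 library 1 that of HMOX1 (up to 0.0568). Among hypoxia genes 4 of 27 rose and 4 fell (6 and 5 adjusted over the list alone; 0.652), with BHLHE40 up from 13.8 ± 0.42 to 17.2 ± 0.04 and the collagen cross-linking enzyme LOX down from 0.803 ± 0.037 to 0.223 ± 0.01 (not tested without any of the empty vector libraries).

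Among genes of chromatin and energy supply, the histones HIST1H2BK (71.2 ± 2.0 to 48.6 ± 3.0 FPKM, SD, n = 3) and HIST1H1C (59.9 ± 3.3 to 44.4 ± 1.8) fell. In all, 5 of 22 replication-dependent histones fell and 0 rose, the same adjusted over the list alone (adjusted p = 0.342). The libraries were polyA-selected, so these values do not stand for histone RNA without a polyA tail. The Polycomb genes EZH1 (3.29 to 4.80) and BMI1 (18.1 to 14.3) moved apart, with 3 of 25 in the PRC2 and chromatin list higher and 1 lower (4 and 1 adjusted over the list alone; 0.98). NDUFB10 of respiratory complex I fell from 115.9 ± 1.0 to 89.0 ± 4.9 and NDUFC2 rose from 22.4 to 27.9, the only calls among 59 nuclear oxidative phosphorylation genes, with the same counts adjusted over the list alone (0.193). That list passed as lower without empty vector library 1 (0.0288) or LINC00888 library 3 (0.0074). Over all libraries it did not pass with an estimated correlation (0.812), and after cyclic loess its direction turned to higher (0.557). The call of NDUFC2 was lost without empty vector library 1 or 2 or LINC00888 library 2 or 3 (up to 0.0664). Of 13 mitochondrially encoded genes 0 passed, the same adjusted over the list alone (0.534), and after cyclic loess the list passed as higher (0.00122), though not with an estimated correlation (0.465 after cyclic loess and 0.866 without it). Among 75 cytosolic ribosomal protein genes 1 rose and 2 fell, RPS2 (417 to 358) being lower and RPS3A (176 to 242) higher, and 0 passed adjusted over the list alone (0.193). The direction of the ribosomal list was not stable: it was lower without empty vector library 1 (0.0375) or LINC00888 library 3 (0.000842) and higher after quantile normalization (0.0111) or cyclic loess (0.00122). With an estimated correlation it did not pass (0.866, and 0.717 after cyclic loess). RPS2 and RPS3A lost their calls without each library but empty vector library 1 (up to 0.0676 and 0.0918), and their reads can be shared with processed pseudogenes. RPS2 and NDUFB10 lie in a stretch of chromosome 16 in which 107 of 140 genes had a lower estimate.

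Among stress and immune genes, the p53 target TP53INP1 rose from 16.4 ± 0.76 to 22.6 ± 1.52 FPKM (SD, n = 3; adjusted p = 0.00995) and the chemokine CCL20 fell from 2.13 ± 0.25 to 0.726 ± 0.07 (adjusted p = 0.00333). The lists themselves did not pass. Of 27 p53 targets 3 rose and 5 fell (5 and 9 adjusted over the list alone; adjusted p = 0.282). Of 22 apoptosis regulators 3 fell, the same adjusted over the list alone (0.55), among them BAX (12.2 to 9.58) and CASP8 (5.16 to 3.80). The unfolded protein response had 2 of 26 higher, PDIA4 (229 to 256) and CRELD1 (4.60 to 5.92), and 2 lower, the same adjusted over the list alone (0.375). The integrated stress response and amino acid list had 3 of 33 higher, with STC2 at 19.4 and 23.6, and 4 lower, with the glutamine transporter SLC1A5 at 45.7 and 39.3 (4 and 6 adjusted over the list alone; 0.193). The lysosomal enzymes CTSB (10.8 to 13.1) and TPP1 (11.8 to 13.8) rose, among 3 rises and 2 falls in 30 autophagy and lysosome genes, the same adjusted over the list alone (0.98). Of 27 interferon-stimulated genes 2 rose, IFI44 (1.22 to 2.29) and CMPK2 (1.58 to 2.12), and 2 fell, the same adjusted over the list alone (0.652). In MHC class I presentation 1 of 13 rose, HLA-B (15.8 to 18.0), and 1 fell, TAP1 (5.32 to 4.45; 2 and 1 adjusted over the list alone; 0.822). In the TNF and NF-kB response 1 of 17 rose and 2 fell, CCL20 and NFKBIA (54.5 to 41.9), the same adjusted over the list alone (0.285). Without 1 library the highest adjusted p was 0.0529 for BAX and 0.0518 for IFI44 (both lost without LINC00888 library 1), 0.0524 for SLC1A5 (lost without LINC00888 library 1) and 0.0505 for STC2 (lost without empty vector library 3). It was 0.0766 for CMPK2, 0.137 for TAP1 and 0.0883 for TPP1, each lost without any of the 6. CASP8 was lost without each library but empty vector library 3 (up to 0.0884). CRELD1 and HLA-B were lost without each but empty vector library 2 (up to 0.0757 and 0.0753), and PDIA4 was lost without empty vector library 1 or 3 or LINC00888 library 2 or 3 (up to 0.0707). NFKBIA was lost without empty vector library 2 or any LINC00888 library (up to 0.078) and CTSB without empty vector library 3 or any LINC00888 library (up to 0.0569). Cyclic loess ended the call of CMPK2, and PDIA4 was not called by eBayes without trend and robust.

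Among signalling genes, the phosphatase DUSP1, which acts on MAP kinases, rose from 13.1 ± 0.69 to 18.2 ± 0.99 FPKM (SD, n = 3; adjusted p = 0.00889). Its relative DUSP4 rose from 4.56 ± 0.03 to 6.42 ± 0.15, and PHLDA1 fell from 6.88 ± 0.19 to 3.99 ± 0.10. The NOTCH ligands moved apart, DLL1 rising from 1.09 to 1.80 and JAG1 falling from 4.23 to 2.74, and the WNT target ASCL2 rose from 3.14 to 4.65. Of 17 immediate early genes 4 rose and 2 fell, the same adjusted over the list alone (adjusted p = 0.901). Of 8 MAPK output genes 1 rose and 2 fell (2 and 2 adjusted over the list alone; 0.622) and of 14 NOTCH genes 2 rose and 1 fell (2 and 3 adjusted over the list alone; 0.698). Of 13 WNT targets 3 rose and 0 fell (5 and 0 adjusted over the list alone; 0.193), with TNFRSF19 at 72.2 and 84.3, a call lost without empty vector library 3 or LINC00888 library 1 (up to 0.0553). In the TGF-beta response 2 of 19 rose and 1 fell (2 and 3 adjusted over the list alone; 0.768), with LTBP2 up from 0.866 to 1.69 and ID3 down from 43.4 to 36.6. Of 12 YAP targets 1 fell, CYR61 (4.97 to 3.66), and 0 rose, the same adjusted over the list alone (0.74).

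Matrix and adhesion genes were mixed. Fibronectin fell, as did the intermediate filament protein vimentin, VIM (3.31 to 1.64 FPKM, chosen after its values were seen), while the laminin LAMB1 rose from 8.17 ± 0.37 to 12.1 ± 0.24 (SD, n = 3; adjusted p = 0.00379). Of 13 mesenchymal (EMT) genes 3 rose and 4 fell (4 and 4 adjusted over the list alone; adjusted p = 0.527), and of 17 integrin and matrix genes 4 rose and 2 fell (4 and 3 adjusted over the list alone; 0.98). Of 18 adhesion and cadherin genes 2 rose and 1 fell, the same adjusted over the list alone (0.975), with the desmosomal cadherin DSC2 at 5.30 and 6.84 and plakoglobin, JUP, at 54.7 and 47.0. DSC2 lost its call without each library but empty vector library 1 (up to 0.0738), and JUP lost its call without each but LINC00888 library 2 (up to 0.0738) and under quantile normalization and cyclic loess.

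In all, 7 of 38 lists with enough members passed camera, each lower with LINC00888, and 0 passed with an estimated correlation (5 at an unadjusted p under 0.05; smallest adjusted p = 0.0702). With fry, which asks whether the members move one way on balance, 11 passed. Its p-values depended on the order of the library columns, with 9 to 13 lists past the threshold over the 720 orders. With its mixed test, which asks whether members change in either direction, 36 passed; neither test compares a list with other genes. The median, the mean and the camera direction did not all have the same sign in 13 lists, none of them past the threshold. These were the histone, luminal, steroid metabolism, mesenchymal (EMT), apoptosis, MAPK output, fatty acid oxidation, interferon, NOTCH, YAP, TGF-beta, autophagy and PRC2 lists.

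At the transcript level, the largest changes took in an apparent exchange between listed transcripts of the focal adhesion protein vinculin. Transcript FPKM rest on how the submitters' software shared reads among the transcripts of a gene. Whether the changes below arose in that step was not tested. Gene values are not sums of their transcripts: per library, transcripts summed to between 312607 and 327293 FPKM and genes to between 211148 and 217637. A transcript can thus stand above its gene, as HDAC2-201 does below. A steady gene value therefore does not show an exchange at a constant gene level. VCL-202 fell from 29.8 ± 2.3 to 2.19 ± 0.30 FPKM and VCL-201 rose from 0.0622 ± 0.029 to 27.7 ± 0.86 (SD, n = 3; adjusted p = 0.00152 and 0.000199). The gene stood at 19.4 and 16.7 (adjusted p = 0.0764). HDAC2-201, of the histone deacetylase HDAC2, was listed at 0 in the 3 empty vector libraries and at 48.0, 33.3 and 63.1 with LINC00888 (adjusted p = 0.00183), with the gene at 10.9 and 10.7 (adjusted p = 0.763). SDAD1-203 was listed at 0 in the empty vector group and at 17.2, 18.4 and 14.4 with LINC00888, and ZCCHC10-202 at 7.44, 9.12 and 8.40 in the empty vector group and 0 with LINC00888. THOC5-206, of the mRNA export complex THO, fell from 26.2 ± 0.80 to 0.258 ± 0.032, and its gene from 9.38 to 6.72 (adjusted p = 0.00428). THOC5-206 and NIPSNAP1 both lie on the minus strand of chromosome 22. The transcription start of THOC5-206, at 29951205, lies within NIPSNAP1, whose downstream end is at 29950797. The others were STAG2-205 (0.159 to 21.2), CLDND1-222 (0.316 to 14.8), TMEM184B-201 (7.95 to 0.00322) and PGAP2-225 (8.04 to 0.272).

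Among 26941 transcripts 102 passed limma's test, 45 higher and 57 lower, and 74 of these changed at least 2-fold in the fit. Of the called transcripts, 43 belonged to tested genes that did not pass and 16 were listed at 0 in all 3 libraries of a group. With the replicate number as a block limma called 0 transcripts, with 2362 at an unadjusted p under 0.05. Leaving out 1 library left 30, 45 and 30 calls (empty vector libraries 1 to 3) or 38, 25 and 22 (LINC00888 libraries 1 to 3). It ended the calls of STAG2-205 (without empty vector library 1 or 2, up to 0.0824), CLDND1-222 (without each but empty vector library 1, up to 0.187), PGAP2-225 (without each but LINC00888 library 1, up to 0.162) and TMEM184B-201 (without each LINC00888 library, up to 0.0772). With 1 library fewer, HDAC2-201, SDAD1-203, VCL-201 and STAG2-205 fell below the filter, and were not tested, without any of the LINC00888 libraries, and THOC5-206, ZCCHC10-202 and TMEM184B-201 without any of the empty vector libraries. Between 7 and 13 of the calls were lower without an empty vector library and between 17 and 30 without a LINC00888 library. The calls of STAG2-205, CLDND1-222 and PGAP2-225 were also lost with a pseudocount of 0.1.

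Near LINC00888 itself, on chromosome 3 at 183447608 to 183456013 of GRCh38, 3 of 21 tested genes passed, where 13.5% of all tested genes did. KLHL24, a ubiquitin ligase adaptor, rose from 4.40 ± 0.02 to 6.32 ± 0.49 FPKM (SD, n = 3; adjusted p = 0.00992). The translation initiation factor EIF2B5 rose from 9.22 ± 0.57 to 11.2 ± 0.31 (adjusted p = 0.0315), and the peptidase ECE2 fell from 3.15 ± 0.27 to 2.43 ± 0.15 (adjusted p = 0.0489). Of 33 protein-coding genes annotated within 1 Mb, 21 were tested and 18 did not pass, with a median log2 fold change of -0.02. Leaving out 1 library ended the calls of EIF2B5 (without each but empty vector library 2, adjusted p up to 0.101) and ECE2 (each of the 6, up to 0.132), and the replicate block ended both (0.0658 and 0.0955). As a list the neighbours did not pass limma's camera (lower, n = 21 genes, p = 0.907). The direction turned to higher with no filter (0.904), the stricter filter (0.884), quantile normalization (0.723), cyclic loess (0.667), and without empty vector library 1 (0.984) or 3 (0.842) or LINC00888 library 1 (0.995) or 3 (0.863).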

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

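Cyclic loess normalization, the fit without genes that span 2-fold within a group, and the fit without part of chromosome 16 were chosen after the results were seen. Across the alternatives run, 0 genes and 0 transcripts called in the data as reported changed direction, and 0 of 140 named features did, where tested. The call of 1581 genes stayed within 1.5 times under both pseudocounts, both filters, all 3 scalings and eBayes without trend and robust (between 1336 and 1586 genes), and was 1912 without genes that span 2-fold within a group and 1523 without chromosome 16 up to 35 Mb. A 2-fold minimum left 42 genes (19 higher, 23 lower) and 74 transcripts (38 higher, 36 lower). That count rests on the pseudocount: 90 genes and 55 transcripts changed at least 2-fold with 0.1, and 21 genes and 70 transcripts with 1. The replicate number as a block, which costs degrees of freedom, left 429 genes (229 higher, 200 lower) and 0 transcripts (0 higher, 0 lower; limma, 2362 at an unadjusted p under 0.05), and 62 of 140 named features lost their call. Same-numbered libraries of the groups did not deviate together across genes (r = 0.0377, 0.0222 and -0.0347), so the numbers were not taken as pairs.

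With fewer libraries, leaving out 1 gave 536 to 815 genes (284 to 487 higher, 252 to 329 lower), each of the 6 moving the count by over 1.5 times, and 22 to 45 transcripts (5 to 32 higher, 7 to 30 lower). Of 127 named genes past the threshold, 69 passed in all 6 such fits and 54 were lost in at least 1. The other 4 (TMEFF2, CTAG2, RIOX1 and LOX) passed in the 3 fits that kept all empty vector libraries and fell below the filter in the rest. The filter also left 84 of the 102 called transcripts tested without an empty vector library and 82 without a LINC00888 library. Leaving out a library gave 6 to 9 lists past the threshold. The heat shock, MYC target, proteasome, G2/M and splicing lists passed in all 6 of these fits. The androgen response list ranged from 0.0165 to 0.0676 in adjusted p (lost without empty vector library 1, 0.0542, and LINC00888 library 2), and the glycolysis list from 0.0337 to 0.061 (lost without empty vector library 1, 0.0542, empty vector library 2, 0.0589, and LINC00888 library 1). The neighbours of LINC00888 (limma's camera, n = 21 genes) ranged from p = 0.732 to 0.995, with the direction turned without empty vector library 1 or 3 or LINC00888 library 1 or 3.

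Of the gene lists, 0 passed camera with an estimated correlation (5 of 38 at an unadjusted p under 0.05), with adjusted p = 0.113 for heat shock, 0.0702 for MYC targets and for G2/M, 0.376 for proteasome and for splicing, 0.309 for androgen response and 0.333 for glycolysis, and 11 passed fry (9 to 13 over the 720 orders of the library columns). The stricter filter ended the androgen (0.0503) and glycolysis (0.0579) calls, median ratio scaling (0.0537) and the replicate block (0.0544) that of glycolysis. Quantile normalization and cyclic loess ended the calls of splicing (0.289 and 0.237), androgen response (0.532 and 0.481) and glycolysis (0.544 and 0.557). Over all alternatives with camera adjusted p ran from 0.000664 to 0.376 for splicing, 0.0165 to 0.532 for androgen response and 0.0337 to 0.557 for glycolysis. With fry, which does not compare a list with other genes, it was 0.0317, 0.00135 and 0.0152. The direction of the neighbours (n = 21 genes) turned with no filter (p = 0.904), the stricter filter (0.884), quantile normalization (0.723) and cyclic loess (0.667). Apart from the fits with fewer libraries or degrees of freedom, the cause was not tested here. The level of LINC00888 and a fit of counts with DESeq2 were not run, since the tables hold FPKM of protein-coding features. Depth is unknown, and in simulated data 2-fold changes were recovered for 80% of genes and for 8% of transcripts, which limits what missing calls mean.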

Other observations

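The tests of length and GC content, of overlapping genes, of the genes left out on chromosome 16, and of the splicing, androgen and glycolysis lists one by one were chosen after the result was seen, as were the families and the genes named in the next 2 paragraphs.

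Among 122 families of genes that share a symbol stem, 1 passed camera. This was MRPL, proteins of the large mitochondrial ribosomal subunit, called lower with LINC00888 (adjusted p = 0.0236), with 2 of 49 members past the threshold, MRPL18 and MRPL51. It did not pass after cyclic loess (adjusted p = 0.367), where GAGE (0.0214) and RPL (0.00137) passed as higher, or with an estimated correlation (0.951; smallest of any family 0.847). The families CDC (4 of 30 fell), TIMM (2 of 15 fell) and PSMD (1 of 14 fell) did not pass (adjusted p = 0.0504 each). Nor did the small subunit family MRPS (4 of 29 fell) or the COL family (6 of 15 rose), also at 0.0504. The intraflagellar transport family IFT (3 of 14 rose), which builds cilia, did not pass either (0.0504). After cyclic loess MRPS, COL and IFT stood at 0.367, 0.306 and 0.243. Members past the threshold included MRPS34 (63.0 to 50.8 FPKM), which lies in the run of lower genes on chromosome 16, MRPS12 (29.8 to 24.9), COL6A2 (7.71 to 11.1), COL6A1 (24.9 to 33.8), COL5A2 (0.864 to 1.46), IFT81 (4.28 to 5.60), IFT46 (3.35 to 4.21) and IFT74 (9.68 to 11.03). Quantile normalization and cyclic loess ended the calls of MRPL18 (adjusted p up to 0.072), MRPL51 (up to 0.104), IFT46 (up to 0.076) and IFT74 (up to 0.0532), and median ratio scaling that of IFT74 (0.0617). Leaving out 1 library ended the calls of MRPL18, MRPL51 and IFT74 (each of the 6, adjusted p up to 0.0841, 0.128 and 0.125). It also ended those of IFT46 (all but LINC00888 library 3, up to 0.115), IFT81 (empty vector library 1 or 3 or LINC00888 library 1 or 2, up to 0.0628). The same held for COL6A1 (empty vector library 2 or 3 or LINC00888 library 1, up to 0.0622) and COL5A2 (empty vector library 3 or LINC00888 library 2 or 3, up to 0.0562).

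SESN3 and KLHL24, both higher with LINC00888, are known targets of FOXO transcription factors. A list of other FOXO targets, written after these genes were seen, was higher as a group (camera p = 0.0399 over 24 tested genes; p = 0.0168 after cyclic loess; p = 0.0849 with an estimated correlation). Over the same 24 genes camera no longer passed without empty vector library 1 (0.0827) or LINC00888 library 3 (0.0812). Higher FOXO output is a hypothesis that these data cannot decide, since FOXO activity was not measured. Of these 24, TNFSF10, ATG14 and RBL2 rose and TXNIP fell, the last against that reading, where 13.5% of all tested genes passed. With 1 library fewer, calls were lost for RBL2 (without each of the 6, adjusted p up to 0.0732), ATG14 (all but empty vector library 2, up to 0.0744) and TXNIP (each empty vector library or LINC00888 library 3, up to 0.0643). The replicate block ended all 4, TNFSF10 at 0.0521, and quantile normalization and cyclic loess that of ATG14 (0.0517 each).

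The first pattern weighed is the fall of 7 gene lists, in data where the median fold change ran from 0.12 in the lowest decile of expression to -0.05 in the highest. That trend does not account for all of it: after cyclic loess, which removes the trend, 4 lists still passed (heat shock, adjusted p = 5.83e-08; MYC targets, 8.94e-05; proteasome, 0.00392; G2/M, 0.00122), each with a median below 95% of lists matched on expression. With an estimated correlation none of the 4 passed, before the correction (adjusted p = 0.113, 0.0702, 0.376 and 0.0702) or after it (0.106, 0.121, 0.717 and 0.294). The splicing list lost its call after the correction (median -0.13 before and -0.08 after, with an SD across members of 0.155 and 0.157), so its shift shrank while the spread stayed close, and 0.02% of matched lists lay as low as before the correction. For androgen response (median -0.03 to -0.01, SD 0.30 to 0.31) and glycolysis (-0.08 to -0.02, SD 0.22 to 0.21), 47.4% and 11.7% of matched lists lay as low. By the median, the trend may account for their calls. Their means went from -0.0856 to -0.0615 and from -0.0649 to -0.0296, and that of the proteasome list, which kept its call, from -0.118 to -0.0788. Members of both lists moved both ways, so their medians decide little, and the question stays open. Transcript length and GC content left the trend in place (slope 0.942 times that without them). Empty vector libraries also differed by such a trend: library 1 minus the others ran from 0.041 in the lowest decile to -0.036 in the highest, and library 2 from -0.025 to 0.039. The source of the trend between the groups, in the cells, in the library preparation or in differences between the sublines, stays open.

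The second pattern is the set of genes with at least a 2-fold change in the fit. FPKM values of some genes jump within a group (147 of 4820 genes with a mean FPKM of at least 8 span 2-fold), but jumps at random should part any 3 libraries from the other 3: 8 genes had a 2-fold gap in the real split (NIPSNAP1, ADNP, SESN3, LPL, DCTN4, ARPC5, SLC22A3 and R3HDM4), against at most 2 in any of the other 9 splits. Reads shared with an overlapping gene on the same strand are unlikely for most: 28.6% of the 42 genes had such an overlap (12 genes; exact 95% interval 15.7% to 44.6%), against 34.1% of other genes (Fisher's exact test, two-sided p = 0.517), and for those 12 it stays open. Reads moved from THOC5-206 to NIPSNAP1 could supply 0.114 of the gain of NIPSNAP1, by FPKM times length. The comparison of splits covers those 8 genes as a set, and for the rest of the 42 jumps at random stay open. Splits do not address a shift in quantification shared by all 3 libraries of a group. At the transcript level, 16 calls were listed at 0 in all 3 libraries of a group. Whether such a shift lies behind changes of genes was not tested and stays open. An effect of LINC00888, a difference between the sublines that arose for other reasons and a difference in library preparation also remain. The design cannot tell these apart, since the sublines coincide with the groups.

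The third pattern is a run of lower genes on chromosome 16, from 1560428 to 18573533 in the positions of the tables, where 107 of 140 genes (76.4%, against 42.5% of other genes) had a lower estimate, 28 of them calls, with a median log2 fold change of -0.12. It held 8 of the 13 windows of 40 genes (of 1090) beyond the 95% limit of shuffled genomes. The others were lower ones on chromosome 10 (2, medians -0.165 and -0.145, where CDK1, BMI1 and VIM lie) and chromosome 3 (2, -0.142 and -0.140) and a higher one on chromosome 1 (0.151), which were not tested further. The run was chosen for its low values, so it was chosen again from alternate genes along the genome, with each of the resulting sets in turn, and measured in the 218 genes left out of the choice. Since the run holds 140 genes, the stretches chosen this way took in genes beyond its ends. Values of the left-out genes describe those wider stretches. Of 10000 gene sets matched to 215 of these on GC content, length and expression, 0% had a median as low as theirs (-0.075), which argues against these 3 properties. Without the trend, left-out genes of low, middle and high expression were all lower (medians -0.0895, -0.144 and -0.134; SE 0.039, 0.030 and 0.026). A difference in copy number between the sublines may account for this. Loss of 1 of 4 copies in every cell would give -0.42, copy number was not measured, and regulation of the region by LINC00888 stays open.

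With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1581 genes and the highest other 9, and 102 transcripts and the highest other 53; in both cases 1 split, the real one, gave as many.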
